A study of Homo sapiens with 3 samples.

How the data were processed

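RNA-seq of total RNA from MCF-7 cells was used from 3 libraries, 1 transfected with luciferase siRNA (siLuc) and 2 with EPIC1 siRNA (siEPIC1), each at 40 nM for 72 h, per the labels. The values are expected counts per gene as deposited by the authors in 1 table of 60483 gene IDs. Alignment and quantification used STAR and RSEM with the GRCh38 build, per the submitters' processing notes. Their versions, the annotation and the use of strand are not given in the sources used here. RSEM divides reads that fit several genes among them by estimate, so values of near-identical copies (histones, U3 copies, retrocopies) and of overlapping or antisense genes are uncertain. Of the deposited values 86.0% were exactly whole, zeros included and with no tolerance.

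The expected counts were rounded to whole numbers before any count test. A symbol was found for 56321 gene IDs, and 56753 IDs were present in GENCODE 29 (GRCh38), from which positions, gene types and transcript lengths were taken. EPIC1 was matched by its Ensembl gene ID. Totals per library were 23057728, 30133942 and 14518836, so that 1 count is worth 0.0434, 0.0332 and 0.0689 CPM before scaling. TMM factors were 1.03, 1.03 and 0.942. CPM was computed with TMM-scaled totals. Scaling by library totals alone would shift the median gene of siEPIC1 library 2 by -0.12 on the log2 scale.

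The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and the filterByExpr filter, which kept 17393 genes. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. The fit had 1 residual degree of freedom, from the pair of siEPIC1 libraries, and 9.53 prior degrees of freedom. The common biological coefficient of variation was 0.323. The lone siLuc library is assumed to vary like the siEPIC1 libraries. Nothing in the labels says that the siEPIC1 libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical or may come from different siRNA sequences. Standard errors were obtained from the log2 fold change and the F statistic. A size rule without a test counted genes with a log2(CPM + 1) difference from siLuc of at least 1 in the same direction in both siEPIC1 libraries and a mean of at least 1 CPM (14282 genes considered). Since both differences share the siLuc library, 100 sets of unchanged libraries were simulated against a shared control. The simulated spread was estimated from the pair of siEPIC1 libraries.

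Gene lists (27) were tested with camera of limma 3.58.1 on log2(CPM + 1) with a preset correlation of 0.01, adjusted over the lists. Each list's median was also placed among 10000 random lists matched on mean expression. Exact 95% intervals are given for EPIC1, Poisson for its CPM and binomial for its percent of the control level. A count of 0 was given a floor of 3 counts. These cover counting error only. The genes named are EPIC1, MYC, the cell-cycle genes known from the study, up to 12 higher and 12 lower named or protein-coding genes with a mean of at least 5 CPM ranked by the smaller of the library differences in the shared direction, and up to 4 members per list by the same ranking. Some further members and the genes called by a test were named after their values were seen. Groups, tests, gene lists, this rule and most alternatives were fixed before the data were examined.

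Alternatives were other scalings (DESeq2 size factors, library totals, upper quartile), no filter or a mean of at least 5 CPM, pseudocounts of 0.1 and 5, the Wald test of DESeq2 1.42.0 (its 338 genes without an adjusted p were left as such), limma-trend, camera with an estimated correlation, fry, and leaving out each siEPIC1 library. Protein-coding genes only, removal of a trend on transcript length and GC content, and thinning to the smallest total were added after seeing the data. Length and GC content were known for 17224 of the 17393 genes tested.

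The main test was tested on simulated data for siEPIC1 against siLuc with 17393 genes, of which 16902 were tested. It recovered 2 of 50 genes changed 2-fold, 20 of 50 changed 4-fold, 40 of 50 changed 8-fold and 43 of 50 changed 16-fold, with 6 false calls. In a simulation of the same comparison with 16936 genes, the mitosis list lowered by 1 on the log2 scale was recovered (camera adjusted p = 4.81e-31) and 0 of 25 other lists were called. Genes were drawn independently of each other in these simulations. They therefore cannot show how often camera calls a list whose members vary together.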

Results

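Gene expression was measured by RNA-seq of total RNA from MCF-7, an estrogen receptor-positive human breast adenocarcinoma cell line, 72 h after transfection with 40 nM siRNA. One group received an siRNA against luciferase, a gene that human cells lack, and served as the control (siLuc, 1 library). The other received siRNA against EPIC1, a long non-coding RNA that the study linked to MYC and the cell cycle (siEPIC1, 2 libraries). The labels number the siEPIC1 libraries 1 and 2 without saying whether they carry the same siRNA sequence. The summed expected counts were 23057728 for siLuc, 30133942 for siEPIC1 library 1 and 14518836 for siEPIC1 library 2. At least 1 count was given for 26844, 26043 and 25433 genes, respectively. Abundant structural RNAs (the RNA components of the signal recognition particle, of RNase P and of RNase MRP, and the transcription regulator RNA 7SK, 11 gene IDs in all) took 21.3%, 17.9% and 21.97% of the counts.

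The first question was whether EPIC1 RNA was lower after EPIC1 siRNA. EPIC1 (ENSG00000224271.4) is a lincRNA gene on the plus strand of chromosome 22, from 47631674 to 47855600 in GRCh38, and an annotated transcript of it has 9 exons and 1815 nucleotides. The siLuc library held 74 EPIC1 counts, which is 3.11 CPM (counts-per-million; 95% exact Poisson interval 2.44 to 3.91). siEPIC1 library 1 held 18 counts, 0.581 CPM (0.344 to 0.919), or 18.7% of the control level (95% interval 10.5% to 31.6%). siEPIC1 library 2 held 26 counts, 1.90 CPM (1.24 to 2.79), or 61.2% of the control level (37.6% to 96.8%). These intervals cover counting error only. By the intervals of the percent, EPIC1 was lower than in siLuc beyond counting error in both libraries. In library 2 the difference was smaller and this held only narrowly (upper limit 96.8%). The log2 fold change was -1.38 (SE 0.82), and edgeR's quasi-likelihood test over 17393 genes did not call it (Benjamini-Hochberg adjusted p = 1.00). LINC00898, which starts head to head with EPIC1 on the minus strand, had 19, 12 and 8 counts in siLuc and siEPIC1 libraries 1 and 2. These counts are not scaled for the library totals. Library 1 held fewer LINC00898 counts than siLuc from a larger total, so the level was lower there, on few counts and without a test. Library 2 had the smallest total, so its unscaled count does not rank it against the others. The 13 measured neighbouring genes of the same chromosome band had median log2 differences from siLuc of 0.03 in library 1 and -0.26 in library 2, and as a list they were not called (camera adjusted p = 0.687).

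The second question concerned MYC, the transcription factor the study connects with EPIC1, and 4 cell-cycle genes known from the study, which may have been picked on these same libraries. CDC20, CDC45 and CCNA2 were lower in both siEPIC1 libraries. CDC20, an activator of the anaphase-promoting complex, was at 43.1 CPM in siLuc and at 12.3 ± 7.21 CPM in siEPIC1 (SD, n = 2), with a log2 fold change of -1.82 (SE 0.49). CDC45, a part of the replicative helicase, was at 30.2 CPM against 8.44 ± 3.96 CPM (log2 fold change -1.82, SE 0.47). CCNA2, cyclin A2, was at 78.4 CPM against 30.9 ± 9.71 CPM (log2 fold change -1.35, SE 0.39). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was at 225 CPM in siLuc, 494 CPM in siEPIC1 library 1 and 252 CPM in library 2. MYC itself went in opposite directions, from 159 CPM in siLuc to 65.3 CPM in library 1 and 250 CPM in library 2, so that its log2 fold change was -0.01 (SE 0.64). None of the 5 genes passed edgeR over the 17393 genes kept by its filter, and CDC20 passed without a filter on low counts (edgeR adjusted p = 0.0300 over 31578 genes). CDC20, CDC45 and CCNA2 passed when adjusted over the list alone, which is not independent evidence if the study chose them on these libraries. As a list the 5 genes were lower by camera (adjusted p = 0.0044). With an estimated correlation the camera adjusted p = 0.736, in a test that rests on 1 degree of freedom. The correlation estimated for the list was -0.2, so the higher value does not show members that vary together.

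**Figure D1:**
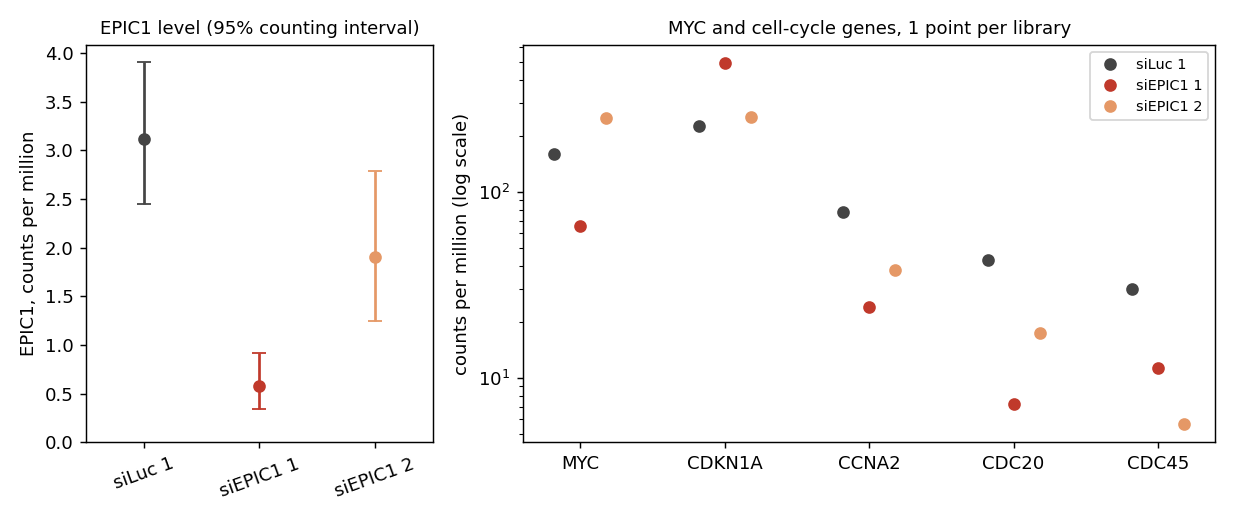
EPIC1 in CPM per library with 95% Poisson intervals (left), and MYC, CDKN1A, CCNA2, CDC20 and CDC45 in CPM on a log axis (right), with 1 point per library. EPIC1 was at 3.11 CPM in siLuc against 0.581 and 1.90 CPM in siEPIC1 libraries 1 and 2, and MYC lay on opposite sides of siLuc in the siEPIC1 libraries.

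The third question was which genes differed from the control across the transcriptome. Among the genes furthest below siLuc in both siEPIC1 libraries were the spindle checkpoint genes MAD2L1 and TRIP13, the mitotic kinesin gene KIF2C, the origin recognition gene ORC1, the cohesion gene CDCA5 and the histone genes H2AC14, H3C13 and H3C14. MAD2L1 was at 50.1 CPM in siLuc and 13.4 ± 1.29 CPM in siEPIC1 (SD, n = 2), which is 3.73-fold lower. TRIP13 was 3.81-fold, KIF2C 3.49-fold and ORC1 3.57-fold lower. The same ranking held CA9, the hypoxia-induced carbonic anhydrase (28.9 CPM against 5.86 ± 1.03 CPM), VGF, a secreted neuropeptide precursor (130 CPM against 24.8 ± 14.1 CPM), STMN3, a regulator of microtubules (94.1 CPM against 23.3 ± 8.24 CPM), and SNORD3B-2, a copy of the U3 small nucleolar RNA (54.4 CPM against 12.9 ± 3.01 CPM). The histone and U3 values are uncertain because near-identical gene copies share reads.

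Among the genes with the highest levels relative to siLuc in both siEPIC1 libraries were TGFB2, a transforming growth factor beta ligand (3.62 CPM in siLuc against 29.6 ± 8.999 CPM, 8.18-fold), UGT1A6, a glucuronosyltransferase whose exons are shared within its locus (7.11-fold), TFPI, the inhibitor of tissue factor (6.01 CPM against 31.6 ± 3.61 CPM, 5.25-fold), and PGM2L1, the glucose 1,6-bisphosphate synthase (12.4 CPM against 64.6 ± 17.1 CPM, 5.20-fold). NEDD9, a scaffold of focal adhesions, was 3.997-fold and SERPINA3, an acute-phase protease inhibitor, 4.05-fold higher. CEACAM6, SULF1, the glycolytic gene PGAM1, RAB29, the p53-inducible gene TP53INP1 and the kinase gene YES1 completed the 12, at 3.89-fold, 3.65-fold, 3.69-fold, 3.59-fold, 3.46-fold and 3.16-fold. PGAM1 has near-identical retrocopies, so its value is uncertain.

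None of these 24 genes passed the filtered edgeR test, where their adjusted p ranged upward from 0.444, and 16 of them passed without a filter on low counts. With 1 control library and 1 residual degree of freedom, edgeR called 1 gene of 17393 at an adjusted p under 0.05, and 833 genes had an unadjusted p under 0.05 (313 higher, 520 lower) where 870 would be expected by chance. The called gene, ENSG00000279576 (edgeR adjusted p = 0.0346), had 279 counts in siLuc and 0 in both siEPIC1 libraries, so it was at least 121-fold lower in library 1 and at least 53.4-fold lower in library 2 against a floor of 3 counts per library. It had no entry in the annotation used here. DESeq2's Wald test called 12 genes, of which TGFB2 (adjusted p = 0.000455), PGM2L1 (0.00845), UGT1A6 (0.00845), TFPI (0.0102), NEDD9 (0.0444), PGAM1 (0.0444) and ERP27 (0.0444) rose, and VGF (0.0444), CA9 (0.0499) and 3 genes without a symbol (ENSG00000279576, ENSG00000260272 and ENSG00000281255) fell. Restricting edgeR to genes with a mean of at least 5 CPM gave 6 calls, and to protein-coding genes 12, while no filter gave 53. CA9, PGM2L1, TGFB2 and VGF were the 4 genes called by DESeq2 and under both restrictions.

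By size alone, 339 of 14282 genes with a mean of at least 1 CPM differed from siLuc by at least 1 on the log2(CPM + 1) scale in the same direction in both siEPIC1 libraries, 109 higher and 230 lower. Of the 230 lower genes, 35 belonged to the DNA replication and mitosis lists and 33 were clustered histone genes. Independent lists of the same sizes would share 10.4 higher and 38.3 lower genes. Both comparisons use the same siLuc library, however, and unchanged libraries simulated against a shared control gave 149 higher genes (range 117 to 181 over 100 draws) and 105 lower genes (79 to 127). The observed number of higher genes was below this simulated level, and that of lower genes above it. Genes were drawn independently in the simulation, so its ranges leave out genes that vary together. Its spread was taken from the siEPIC1 pair, so any real difference between these libraries widens it. Single libraries passed the rule at 1222 genes (library 1) and 1043 genes (library 2), and 17 genes passed it in opposite directions.

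Across genes, the log2 differences of the siEPIC1 libraries from siLuc correlated at r = 0.46, against 0.50 (0.48 to 0.51) in the simulation without any effect. Genes are not independent replicates. The covariance was 0.146 against a simulated 0.160 (0.151 to 0.166), and 64.2% of genes had the same sign against 66.5%. The control library cannot be split. The relation of the siEPIC1 libraries over all genes did not exceed what a shared control gives if it varies like the siEPIC1 pair. That spread includes any real difference between the siEPIC1 libraries, so the simulation cannot exclude an effect that they share. Between themselves the siEPIC1 libraries differed by at least 1 on the log2 scale at 1168 genes (8.18%), with 693 higher in library 1 and 475 higher in library 2.

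**Figure D2:**
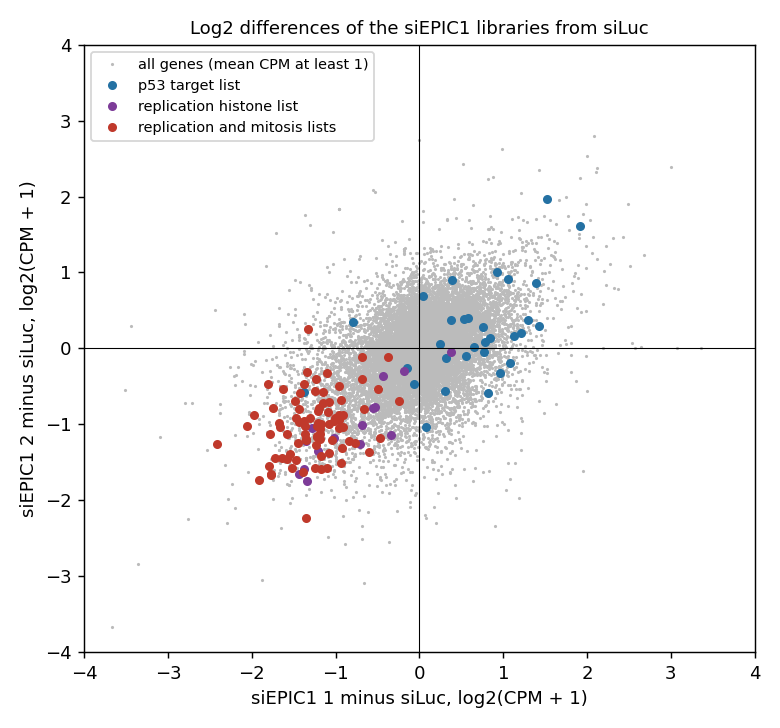
Log2(CPM + 1) difference from siLuc of siEPIC1 library 1 (horizontal axis) and siEPIC1 library 2 (vertical axis) for genes with a mean of at least 1 CPM, with fixed gene lists in colour. Of the 83 replication and mitosis genes (red), 82 lay below 0 in both libraries, while p53 targets (blue) lay mostly to the right of 0.

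Proliferation genes were lower in both siEPIC1 libraries. All 43 measured genes of the DNA replication and G1/S list were lower than siLuc in both siEPIC1 libraries, with median log2 differences of -1.10 in library 1 and -1.13 in library 2, a median 2.14-fold reduction. ORC1 and TK1, the nucleotide salvage kinase of S phase (89.3 CPM against 31.5 ± 0.0427 CPM), MCM10 (62.5 CPM against 21.2 ± 1.34 CPM) and E2F2 (29.3 CPM against 9.34 ± 0.263 CPM) led it. Ranking by the smaller difference favours genes whose siEPIC1 libraries happen to agree. These small SDs therefore do not measure how well the libraries repeat. Of the 40 genes of the G2/M and mitosis list, 39 were lower in both libraries, with medians of -1.40 and -0.97, and MAD2L1, KIF2C, HMMR (28.0 CPM against 8.13 ± 1.13 CPM) and the kinase gene AURKB (15.4 CPM against 4.51 ± 0.764 CPM) led. The exception was CKS2 (-1.34 and 0.25), named after its values were seen. Together the 83 genes included 35 past the size rule, all lower (42.2%), against 195 of 14199 other genes (1.37%).

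By edgeR, 33 replication genes and 26 mitosis genes fell when adjusted over the list alone. Over the 17393 genes of the filtered edgeR test 0 of either list passed, with 36 and 29 at an unadjusted p under 0.05, and DESeq2 called no member. In other edgeR settings mitosis genes fell: MAD2L1 with protein-coding genes only (adjusted p = 0.0389), and MAD2L1 (adjusted p = 0.0147), CDC20 (0.0300) and KIF2C (0.0352) without a filter on low counts. By camera with a preset correlation of 0.01 both lists fell (adjusted p = 2.40e-35 and 5.63e-33), and their medians lay below those of all 10000 random lists matched on expression. The preset and the random lists treat members as nearly independent, so these values do not measure the strength of an siRNA effect. The estimated correlation, which rests on 1 degree of freedom, was -0.02 for the replication list and 0.81 for the mitosis list. With it, the camera adjusted p = 0.736 for each. All of these values are relative to 1 siLuc library, which has no replicate.

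Replication-dependent histone genes, whose RNAs accumulate in S phase and mostly lack poly(A) tails, were lower as well. Of 15 measured members of the fixed histone list 14 were lower in both libraries, with medians of -0.71 and -1.14, and 7 fell by edgeR when adjusted over the list alone. H1-3 was at 66.5 CPM in siLuc and at 24.9 and 21.5 CPM in siEPIC1 libraries 1 and 2, and H1-5 at 72.9, 28.0 and 21.1 CPM. H2BC11 was at 38.2, 13.5 and 11.4 CPM. The list was called by camera (adjusted p = 3.67e-11; adjusted p = 0.736 with an estimated correlation). The list was also chosen as a mark of how RNA was selected for the library. On another such mark, the summed share of structural RNAs, siLuc (21.3%) lay between the siEPIC1 libraries. Its parts went both ways. siLuc was highest for the signal recognition particle RNA (13.9% against 10.9% and 13.7%) and lowest for 7SK (4.27% against 4.76% and 5.51%). These shares do not settle whether RNA selection differed.

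Targets of p53 were higher, more so in library 1. Of 32 measured genes, 20 were higher in both libraries, with medians of 0.77 and 0.18. TP53INP1 (49.5 CPM in siLuc against 171 ± 26.3 CPM) and ZMAT3, an RNA-binding regulator of splicing (28.9 CPM against 100 ± 21.6 CPM), rose when adjusted over the list alone, while SESN1 (39.4, 83.4 and 74.9 CPM) and CCNG1 (110, 211 and 222 CPM) did not pass. PMAIP1 went the other way, at 39.3, 14.5 and 26.0 CPM. The list was called by camera (adjusted p = 7.85e-06; adjusted p = 0.736 with an estimated correlation).

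MYC targets were slightly lower, with medians of -0.48 and -0.13. Of 41 measured genes 26 were lower in both libraries, 0 were higher in both and 0 passed edgeR over the list alone. The ribosome biogenesis gene BOP1 was at 63.2, 33.9 and 38.9 CPM in siLuc and siEPIC1 libraries 1 and 2, and DKC1, the pseudouridine synthase, at 90.6, 60.5 and 58.9 CPM. The camera adjusted p was 0.000397, and with an estimated correlation adjusted p = 0.736.

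Metabolic lists were lower too. In cholesterol synthesis, 16 of 23 genes were lower in both libraries, with medians of -0.43 and -0.91. They included EBP, the sterol isomerase (85.4, 28.3 and 37.1 CPM), MVD (283, 141 and 86.7 CPM) and HMGCS1 (225, 122 and 86.3 CPM), and 0 passed edgeR over the list alone, with 6 at an unadjusted p under 0.05. In hypoxia and glycolysis, 20 of 29 genes were lower in both libraries, with medians of -0.53 and -0.32, and CA9 and the aldolase gene ALDOC (116, 37.9 and 45.0 CPM) fell over the list alone. Camera called both lists (adjusted p = 5.15e-07 and 1.68e-06), and with an estimated correlation adjusted p = 0.736 for each.

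Camera called 4 further lists. Immediate-early genes had medians of -1.06 and -0.05 (adjusted p = 0.00512; adjusted p = 0.736 with an estimated correlation), with EGR1 at 46.6, 12.7 and 23.4 CPM. Ribosomal protein genes had medians of -0.07 and 0.60 and were called higher (adjusted p = 0.00486; adjusted p = 0.870 with an estimated correlation), so library 2 alone gave the direction. Mesenchymal genes had medians of 0.55 and 0.27 and were called higher (adjusted p = 0.00237; adjusted p = 0.736 with an estimated correlation), though many were barely expressed, such as SNAI2 at 0.252, 0.969 and 0.952 CPM. Luminal epithelial genes had medians of 0.22 and 0.21 (adjusted p = 0.0478; adjusted p = 0.736 with an estimated correlation), with GATA3 at 157, 298 and 202 CPM. This last call was lost in 4 other settings (camera adjusted p from 0.05996 to 0.211), among them a pseudocount of 0.1 and a mean of at least 5 CPM.

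The other lists were not called by camera. The estrogen response (medians 0.21 and -0.02), interferon response (0.46 and -0.15), NF-kB and inflammation (-0.15 and 0.44), cyclin-dependent kinase inhibitors (-0.93 and -0.36), the integrated stress and unfolded protein responses (-0.23 and -0.08), heat shock (-0.22 and 0.04), nuclear-encoded oxidative phosphorylation (-0.18 and 0.14), the BCL2 family and apoptosis (0.14 and 0.08), and the RNA silencing machinery (0.15 and 0.17) had adjusted p from 0.135 upward. A list chosen as a mark of RNA quality, which holds small structural RNAs, hosts of small nucleolar RNAs and the long nuclear RNAs MALAT1, NEAT1 and TUG1, had medians of -0.45 and 0.03 (adjusted p = 0.449), and its members went both ways, with MALAT1 at 1572, 3068 and 3295 CPM. The 13 genes encoded by mitochondrial DNA had medians of -0.92 and 0.44 (adjusted p = 0.687). Markers of cells other than luminal ones were basal and myoepithelial genes (0.04 and 0.40, adjusted p = 0.0550), fibroblast genes (0.14 and 0.66, 4 measured) and leukocyte and endothelial genes (-0.19 and 0.06, 6 measured). The basal list was called higher in 3 other settings (camera adjusted p from 0.0154 with a mean of at least 5 CPM to 0.0411), but not in the main setting, where adjusted p = 0.736 with an estimated correlation. CDH3, P-cadherin, was at 84.4, 185 and 206 CPM.

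**Figure D3:**
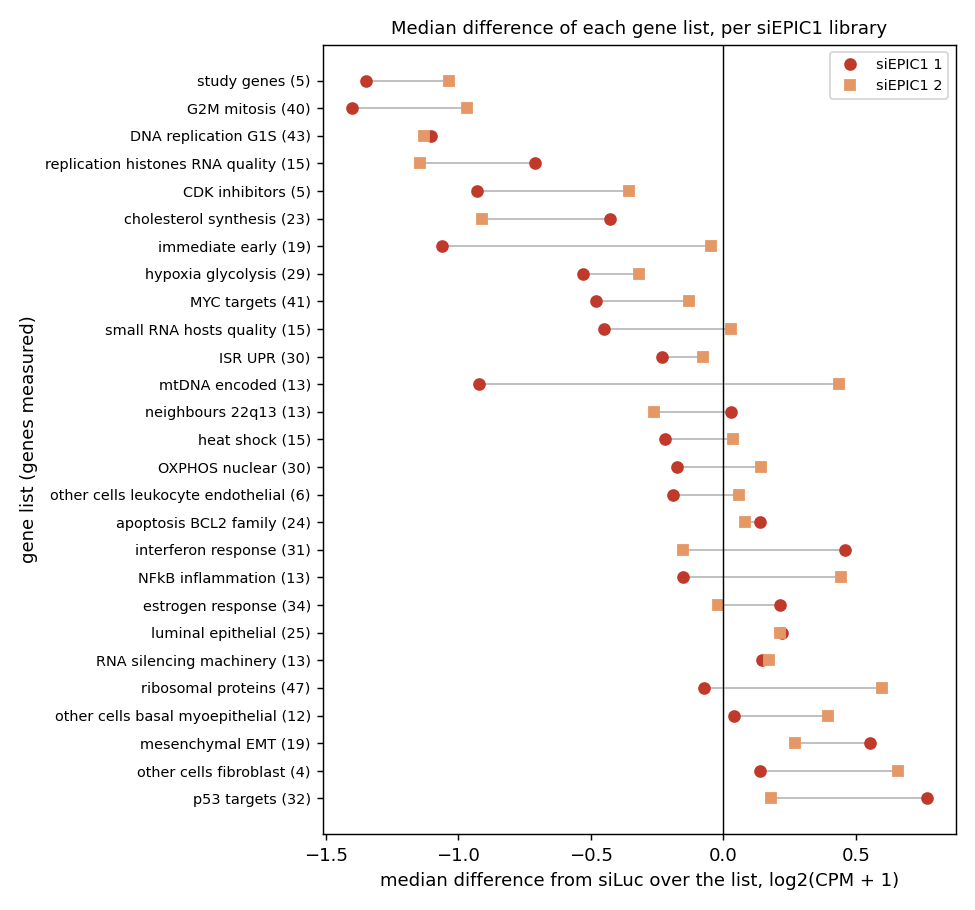
Median log2(CPM + 1) difference from siLuc over each fixed gene list in siEPIC1 library 1 (circles) and library 2 (squares), with the number of genes measured in parentheses. The mitosis (-1.40 and -0.97) and replication (-1.10 and -1.13) lists were far below 0 in both libraries, while mitochondrially encoded genes (-0.92 and 0.44) were on opposite sides.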

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

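Protein-coding genes only, the length and GC trend and thinning were tried after the data were seen. No paired analysis was possible because only 1 siLuc library was used and the labels do not pair it with a siEPIC1 library. The count of genes called by edgeR was 1 in the main setting and with both other scalings, 53 without a filter on low counts (23 higher, 30 lower), 6 with a mean of at least 5 CPM, 12 with protein-coding genes only, 12 by DESeq2 and 0 by limma-trend. Leaving out a siEPIC1 library left no residual degrees of freedom, so no count exists there. The size rule gave 564 genes with a pseudocount of 0.1 and 154 with one of 5, against 339. In a single siEPIC1 library it gave 1043 to 1222, because fewer libraries had to pass. The pseudocount alternatives of the edgeR count applied to normalized values only and were not run. The EPIC1 log2 fold change stayed below 0 in each setting run and was called in none. With library 1 alone the difference was -1.38 on the log2(CPM + 1) scale, and with library 2 alone -0.50. That scale shrinks differences at such low levels, so these values are not comparable with the edgeR fold change. By CPM, libraries 1 and 2 were at 18.7% and 61.2% of siLuc. EPIC1 itself lies under the 5 CPM minimum. Of 27 lists, 12 were called by camera, 0 with an estimated correlation and 0 by fry. The medians of the replication list (-1.10) and the mitosis list (-1.18) are the same there by construction, since these methods use the same log2 values. The adjusted p was 0.736 for both lists by camera with the estimated correlation, and 0.397 and 0.867 by fry, which tests another hypothesis. Both methods rest on 1 degree of freedom here, so hardly any list could pass whatever its correlation. The 0 calls therefore do not decide whether the lists changed. Both stayed called by camera with the preset correlation under the other scaling, pseudocount, filter, gene type, trend and depth settings. Single libraries, for which no test exists, ranged from -1.13 to -1.10 for replication and from -1.40 to -0.97 for mitosis. The ribosomal protein list reversed, from -0.0714 with library 1 alone to 0.60 with library 2 alone. The cause was not tested for the changes above for which none is given. EPIC1 rests on 18 to 74 counts per library, and its siEPIC1 values differ by more than counting error (0.344 to 0.919 CPM against 1.24 to 2.79 CPM).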

Other observations

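Lower histone RNA levels extended past the 15 measured members of the fixed list. Of 57 clustered histone genes measured, a wider set chosen after values were seen, 56 were lower than siLuc in both siEPIC1 libraries and 33 passed the size rule, all lower, with median log2 differences of -1.14 and -1.29. The 42 genes outside those measured members had medians of -1.14 and -1.35. Only 15 of the 32 members of the fixed list were matched to a gene ID, so unmatched members may be among these 42. Replication and mitosis genes and clustered histone genes together made up 68 of the 230 genes lower by size.

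The tests below were planned before their results were seen. The first pattern is the lower level of 83 replication and mitosis genes in both siEPIC1 libraries (medians -1.23 and -1.02). Removing a trend on transcript length and GC content left medians of -1.27 and -0.99, which argues against such a trend as the whole cause. Thinning to equal totals left -1.26 and -1.02. Thinning keeps the expected CPM of each gene, so these medians could hardly move and the role of sequencing depth is not decided. The siRNA and the lone control library cannot be told apart, since the siEPIC1 libraries differ from each other by only -0.20 over these genes and only 1 siLuc library was analysed here. Lower proliferation after EPIC1 siRNA stays a hypothesis, as does a siLuc culture that was growing faster or was less dense, which may give the same values.

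The second pattern is that mitochondrially encoded and ribosomal protein genes lie on opposite sides of siLuc, or nearly so, in the siEPIC1 libraries, with library 1 below library 2 by -1.50 and -0.74 (median log2 differences). After a trend on transcript length was removed they were -1.47 and -0.74, and after one on GC content -1.53 and -0.76, which argues against both trends as the whole cause. Different siRNA sequences in the siEPIC1 libraries may contribute, but the labels do not state them and each library stands alone, so that sequence and library cannot be told apart; 8.18% of genes differ by at least 1 between these libraries.

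The third pattern is the correlation of the log2 differences of the siEPIC1 libraries (covariance 0.146). A control varying like the siEPIC1 libraries would alone give about 0.169, the observed value lies -0.0225 from it, and so the shared siLuc library may account for the correlation over all genes. This does not address the replication and mitosis genes, of which 42.2% were lower by the size rule, against 1.37% of the other genes (histone genes included). As a further check, taking siEPIC1 library 1 or library 2 as the lone library gave 364 and 310 genes by the size rule, against 339 with siLuc alone. The directions differed: relative to the lone library, 109 genes were higher and 230 lower in the other libraries with siLuc alone, 214 and 150 with siEPIC1 library 1 alone, and 227 and 83 with siEPIC1 library 2 alone. The counts 214, 150 and 227 also lay above the ranges simulated with siLuc as the lone library (117 to 181 higher, 79 to 127 lower). No ranges were simulated with a siEPIC1 library as the lone library, and the library totals differ. These counts therefore do not decide whether siLuc stood further apart than the siEPIC1 libraries.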
